A study of Sus scrofa domesticus with 30 samples.

How the data were processed

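Endometrium, the lining of the uterus, was sampled from the middle of the uterine horn of 15 crossbred gilts (young female pigs) on pregnancy day 13. Per the labels, 7 gilts had a low and 8 a high immunocrit (iCrit) on the first day of life, and a further low iCrit gilt that was not pregnant was left out of the study. Each animal gave 1 poly(A)-selected mRNA library, sequenced as paired-end 50 bp reads, and 1 small-RNA library, sequenced as single-end 50 bp reads, both on a HiSeq 2500 from RNA with an integrity number of at least 7.5, per the labels' protocols. The 30 libraries were grouped by the feeding label, and the 2 libraries of an animal were joined by the animal number that their titles share. Animals were numbered within each group in the order of their records, and these numbers only name an animal.

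The authors deposited 1 table of normalized values per assay, and these are treated here as signal: linear values that are never negative, scaled between libraries, with a floor of 1. The aligner, the counting tool, the genome build and the scaling method are not given in the sources used here. The mRNA table held 28224 gene models, of which 10022 were at the floor in every library and 16819 lay above it in at least 7 libraries. The miRNA table held 420 mature miRNA loci, of which 106 were at the floor in every library and 302 passed the same filter. Gene coordinates equalled those of the Sscrofa11.1 gene table for 27579 of the mRNA gene models (97.7%), and for 27553 the symbol was the same as well, so gene coordinates are given in that build. Positions of miRNA loci were not matched to it and are printed as deposited, in a build that is not given in the sources used here. A spreadsheet had turned 26 symbols into dates, and 25 of them were restored by exact coordinates. Names repeated an earlier name in 441 mRNA and 58 miRNA entries. Each entry was tested on its own. The sources used here do not give how reads that match several entries were assigned. Such reads come from identical mature miRNAs at several loci, near-identical let-7 members and ribosomal protein genes with processed pseudogenes. The 2 miR-365-3p loci had equal values in every library (555 at both in low iCrit replicate 1). Reads of such identical miRNAs thus appear to count at each locus rather than being split, so a sum over miRNA loci can hold them more than once. No per-sample column was left unmapped (0 in each table).

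The low values of each library were multiples of 1 library-specific step, the worth of 1 read, which gave an estimate of depth. With a tolerance of 0.05 steps, where random values would reach 10%, 90.3% to 92.8% of low mRNA values and 100% of low miRNA values were whole multiples. The estimate was 23.7 to 63.5 M reads (M, 1e6) for the mRNA libraries and 12.7 to 18.0 M for the miRNA libraries. It sums all entries, so miRNA reads that count at several loci enter it more than once and the miRNA depth may be overstated. Because the floor hides the difference between 0 and 1 read in many libraries and some mRNA values were not whole, read counts were not rebuilt and no count model was fitted. These estimates carry the depth of the libraries, while the errors given below are the spread between animals.

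Values were taken as log2(value + 1), a scale that understates the change of low genes, and tested with limma (version 3.58.1 in R 4.3.3) with an intensity trend, low minus high iCrit, without covariates, since the labels give no batch, litter or sire. Calls needed a Benjamini-Hochberg adjusted p under 0.05 over all features of the assay. Fixed lists, 31 of genes and 9 of miRNAs with at least 3 tested members, were tested with camera in limma with a preset correlation of 0.01, adjusted over the lists. Beside it stand camera with an estimated correlation, fry, which asks whether the genes of a list move one way on balance without comparing them with other genes, and an exact two-sided permutation of the mean per library over all 6435 splits of the animals into 7 and 8. Member counts are given over all genes and adjusted over the list alone. Correlations across animals used 100000 permutations, and within groups an exact permutation test. The spread within groups was compared over 100 draws of permuted labels, and counts of calls were set against 100 splits of the animals drawn with a fixed seed, the real one included. Tables and figures also used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

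The lists, the tests, the other settings and the rule for named genes were chosen before the data were examined. The exact permutation of the list means, the comparison of first components among 11 animals only and the estimate of depth were added afterwards. The rule took, among genes with a symbol and a mean at or above the median tested gene (763), the 12 largest changes past the threshold in each direction. Where fewer than 4 passed, as here, it took the 4 smallest p in that direction, said not to pass. It added up to 4 members with the smallest p of each called list and 14 fixed genes whatever their result, and for miRNAs the same fill to 4 in each direction. A gene named by 2 parts of the rule counts under both. Some genes that the rule names are not reported here.

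The tests were checked on simulated data with the real means and spreads before use. For the mRNA comparison (16818 genes simulated), limma called 19.4% of 67 genes changed 1.5-fold, 47.8% of 67 changed 2-fold and 86.4% of 66 changed 4-fold, with 7 unchanged genes called. The planted list was called and 0 others were, but the noise was drawn for each gene on its own. The simulation therefore cannot show how often camera calls lists whose members vary together, as those of several real lists do. A planted 1.5-fold ratio of spreads came back as 0.57 on the log2 scale. For the miRNA comparison (302 miRNAs simulated), 70% of 10 miRNAs changed 1.5-fold and 100% of those changed 2-fold or 4-fold were called, with 0 unchanged ones called, and the planted spread came back as 0.53.

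The alternatives were other pseudocounts (0.1 and 5), no filter or a stricter one, quantile normalization, median centring, no intensity trend, quality weights per library, robust empirical Bayes, a 1.5-fold minimum, and leaving out each animal in turn. Added after the data had been seen were removal of each library's trend on gene span, the first principal component or the estimated reads as a covariate, 1 entry per mature miRNA name, and fits without libraries that stood apart. Count models were not used because the values are not counts.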

Results

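The data were poly(A) mRNA and small-RNA profiles of the endometrium of 15 gilts on pregnancy day 13, when pig conceptuses elongate and signal to the uterus. The gilts differed in their immunocrit (iCrit) on the first day of life, a blood measure of absorbed immunoglobulin that stands for how much colostrum a newborn piglet took in. The study asked whether too little of this early, milk-borne (lactocrine) signalling is followed by differences in the adult uterus, by comparing 7 low iCrit with 8 high iCrit gilts. Values are the authors' normalized expression values, with no unit beyond their own scale. The estimated depth of the mRNA libraries was 41.3 ± 13.2 M reads (M, 1e6) in low and 34.6 ± 5.22 M in high iCrit gilts (SD, n = 7 and 8, exact permutation p = 0.222). For the miRNA libraries it was 14.8 ± 1.72 and 14.9 ± 1.60 M reads (exact permutation p = 0.934), a sum over loci that can hold the same reads more than once. The 10 most abundant miRNA loci held 61.6 ± 2.24% of the signal in low and 59.5 ± 1.21% in high iCrit gilts (exact permutation p = 0.0401, not adjusted over the library measures compared). These loci can include copies of the same mature miRNA.

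The genes with the smallest p in each direction, among those at or above the median level, differed by less than 2-fold between low and high iCrit endometrium, and none passed the test over all genes. RECK, a membrane-anchored inhibitor of matrix metalloproteinases (chromosome 1, 236821243 to 236898280), had a value of 1753 ± 221.5 in low and 1160 ± 233 in high iCrit gilts (SD, n = 7 and 8), a log2 difference of 0.61 ± 0.13 (SE). BMPER, a secreted regulator of bone morphogenetic proteins (chromosome 18, 39417830 to 39664010), stood at 1154 ± 154 against 817 ± 158. MUM1L1 (chromosome X, 86785317 to 86814631) stood at 2024 ± 413 against 1239 ± 347, and PDS5B, a cohesin regulator (chromosome 11, 9014694 to 9223035), at 2556 ± 255 against 2021 ± 209. On the lower side, AGTRAP, which binds the angiotensin II receptor (chromosome 6, 71825319 to 71836812), stood at 2117 ± 167 in low and 2861 ± 277 in high iCrit gilts, a log2 difference of -0.43 ± 0.08 (SE).

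C9H1orf21 (chromosome 9, 125613082 to 125846002) and BCKDHA, a subunit of the branched-chain keto acid dehydrogenase (chromosome 6, 49381995 to 49398745), were lower in all 7 low iCrit gilts than in any high iCrit gilt, with log2 differences of -0.68 ± 0.14 and -0.44 ± 0.09 (SE). ANAPC15, a subunit of the anaphase-promoting complex (chromosome 9, 6685934 to 6689913), differed by -0.49 ± 0.11. All 7 low iCrit gilts lay beyond the high iCrit mean for each of these 8 genes, which adds no support, since they were picked for the smallest p. Their adjusted p by limma was 0.672, the lowest of all genes tested. limma called 0 of 16819 genes, with 1200 at an unadjusted p under 0.05, where chance would give 841. Of these, 455 were higher and 745 lower in low iCrit gilts, a split that became 600 and 603 after quantile normalization and 569 and 603 after median centring. In simulated data of this size limma called 19.4% of genes changed 1.5-fold and 47.8% of those changed 2-fold.

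Genes of protein synthesis and of mitochondrial respiration tended to lower values in low iCrit endometrium. All 74 cytosolic ribosomal protein genes, the protein part of the ribosome, were lower, with a median log2 difference of -0.29, and 40 of them at an unadjusted p under 0.05. RPS10, a protein of the small ribosomal subunit, stood at 13831 ± 1071 in low and 18994 ± 5009 in high iCrit gilts (SD, n = 7 and 8). Of 41 genes of oxidative phosphorylation 40 were lower, with a median of -0.21. Among its members NDUFV1, NDUFB9, NDUFS8 and NDUFA10, subunits of complex I of the respiratory chain, differed by -0.31, -0.34, -0.32 and -0.32.

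The ribosomal protein list was called by camera (adjusted p = 4.6e-31), but the call did not hold with an estimated correlation (adjusted p = 0.631), since its members moved together across animals. Its mean lay below the high iCrit mean in 7 of 7 low iCrit gilts and gave an exact permutation p of 0.0131, or 0.405 adjusted over the 31 lists. The oxidative phosphorylation list had an camera adjusted p of 5.3e-08 and an adjusted p of 0.8292 with an estimated correlation. In both lists 0 members passed over all genes and 0 adjusted over the list alone, while 40 and 5 members had an unadjusted p under 0.05 by limma. High iCrit replicate 7 had the fewest estimated reads (23.7 M) and an oxidative phosphorylation mean of 0.68 above the average of all libraries. Without the 3 libraries apart, which are that animal, low iCrit replicate 2 and high iCrit replicate 8, the oxidative phosphorylation median was -0.02 and its adjusted p 0.282.

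**Figure D1:**
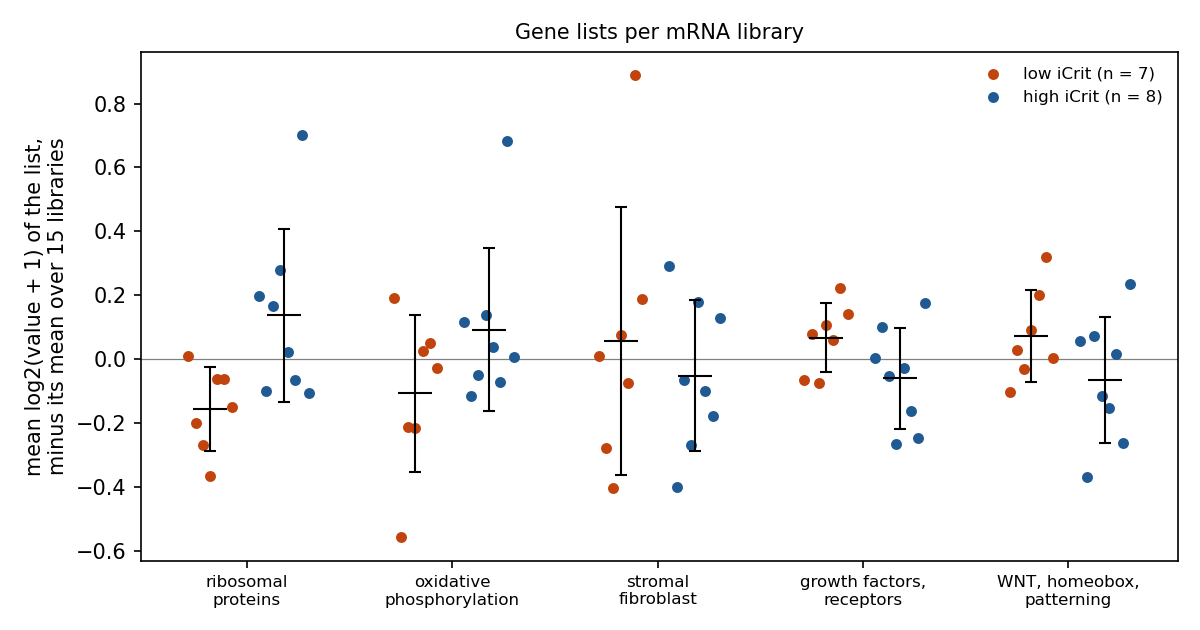
Mean log2(value + 1) of each called gene list per mRNA library, centred on the mean of the 15 libraries (vertical axis, log2 units), for low iCrit (n = 7) and high iCrit (n = 8) gilts. Points are animals, bars give the group mean ± SD, and the ribosomal protein list stands at -0.16 ± 0.13 in low and 0.14 ± 0.27 in high iCrit gilts, with high iCrit replicate 7 above the others.

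Most genes in lists tied to tissue growth and patterning had a higher value in low iCrit endometrium, by little and with exceptions. In the WNT, homeobox and uterine patterning list 31 of 50 genes were higher (median 0.15), among them DKK1, a secreted WNT antagonist (2018 ± 546 in low, 1264 ± 515 in high, SD, n = 7 and 8), FZD4, a WNT receptor (946 ± 174 and 710 ± 153), WNT2 (529 ± 223 and 337 ± 110) and HOXA10, a homeobox gene of uterine receptivity (1204 ± 316 and 895 ± 262). Of the growth factors and their receptors 34 of 50 were higher (median 0.12), with PDGFRA at 7463 ± 1347 against 5223 ± 1075, FGFR2 at 5052 ± 1616 against 3404 ± 616, FGF10 at 726 ± 202 against 539 ± 148 and LIF at 2242 ± 746 against 1523 ± 953. Of the stromal fibroblast markers 18 of 23 were higher (median 0.20), including LUM at 10190 ± 2432 against 8130 ± 858 and FBLN1 at 8265 ± 2848 against 6276 ± 1227, a log2 difference of 0.36 that was 0.22 without low iCrit replicate 6. THY1 went against that list, at 6037 ± 8772 against 16881 ± 13542.

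The lists of WNT, homeobox and uterine patterning genes, of growth factors and their receptors and of stromal fibroblast markers were called by camera with adjusted p of 0.0156, 0.0137 and 0.0137. With an estimated correlation their adjusted p were 0.631, 0.631 and 0.8292. No member passed over all genes or adjusted over the list alone (0 in each), with 5, 3 and 2 members at an unadjusted p under 0.05 by limma, all higher. Low iCrit replicate 6 had the highest value of these lists in its group, and without it the adjusted p were 0.120, 0.123 and 0.544 and the medians 0.12, 0.09 and 0.05. The patterning call was also lost without low iCrit replicate 5 (0.0580), high iCrit replicate 2 (0.147) or high iCrit replicate 7 (0.0520, with a median of 0.096), and the stromal call without high iCrit replicate 2 (0.147). With quality weights per library all 3 calls were lost (0.169, 0.168 and 0.379), and the patterning call also with the stricter filter (0.0735) and with estimated reads as a covariate (0.119).

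Hormone receptors and the genes known from lactocrine work in newborn gilts did not pass the test over all genes. ESR1, the estrogen receptor, stood at 6815 ± 941 in low and 7063 ± 2839 in high iCrit gilts (SD, n = 7 and 8) with a log2 difference of the opposite sign (0.03 ± 0.20, SE), PGR, the progesterone receptor, at 278 ± 29.6 and 298 ± 102, and RXFP1, the relaxin receptor, at 1508 ± 872 and 1441 ± 691. VEGFA, a vascular growth factor, stood at 4429 ± 1997 and 3750 ± 1126, WNT7A at 104 ± 68.3 and 85.7 ± 100 (log2 difference 0.62 ± 0.56, SE), and MMP9, a matrix protease, at 13.5 ± 6.28 and 14.0 ± 8.37. FOXA2, a transcription factor of uterine glands, stood at 2326 ± 793 and 2860 ± 364, a log2 difference of -0.36 ± 0.17 (SE, limma adjusted p = 0.703). The FOXA2 difference was -0.23 without low iCrit replicate 1 and -0.49 without low iCrit replicate 2, and the WNT7A difference was 0.36 without high iCrit replicate 6, 0.38 without low iCrit replicate 7 and 0.98 without high iCrit replicate 8. The list of relaxin receptor and lactocrine-sensitive genes had 13 of 21 members higher (median 0.04, camera adjusted p = 0.396).

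Genes that respond to conceptus estrogen varied more between animals than between groups. SLC5A1, a sodium-glucose transporter, stood at 7304 ± 6057 in low and 14183 ± 9025 in high iCrit gilts (SD, n = 7 and 8, limma adjusted p = 0.719). STC1, a calcium-regulating hormone, stood at 3898 ± 4321 and 6238 ± 4374, LPAR3, a receptor for lysophosphatidic acid, at 1919 ± 2803 and 1568 ± 1098, and FGF7, an epithelial growth factor, at 18086 ± 11609 and 11862 ± 2113. PTGS2, which makes prostaglandin precursors, stood at 7580 ± 3687 and 6905 ± 2563, and SPP1, an adhesion protein of implantation, at 1949 ± 609 and 2599 ± 2225. On the log2 scale PTGS2, SPP1 and LPAR3 differed by -0.03, -0.07 and -0.71, so for PTGS2 and LPAR3 the low iCrit mean was the higher while the log2 difference was negative. The list of conceptus-estrogen and receptivity markers had 11 members higher and 16 lower, with a median of -0.07 and a mean of -0.19, while camera pointed upward (adjusted p = 0.907). Without low iCrit replicate 2, where its mean lay at -1.39, the SLC5A1 difference went from -1.34 to -0.77 and the LPAR3 difference from -0.71 to -0.28, and without low iCrit replicate 6 they went to -1.65 and -1.27. The FGF7 difference of 0.35 was 0.11 without low iCrit replicate 1 and 0.68 without low iCrit replicate 2, and the STC1 difference of -1.19 was -0.79 without low iCrit replicate 6.

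In steroid metabolism, HSD17B8 and HSD17B10, both hydroxysteroid dehydrogenases, were the members that passed when adjusted over the list alone (2 members, both with an adjusted p of 0.0457), against 0 over all genes. HSD17B8 stood at 1014 ± 120 in low and 1396 ± 255 in high iCrit gilts (SD, n = 7 and 8) and HSD17B10 at 1433 ± 132 and 1973 ± 413. The list as a whole was not called (19 of 33 lower, median -0.07, camera adjusted p = 0.533). Among the solute carriers of nutrient transport SLC38A4, an amino acid transporter, stood at 228 ± 51.4 in low and 109 ± 44.9 in high iCrit gilts (1 member with an adjusted p = 0.0188 over the list alone, against 0 over all genes). That list had 25 of 48 members lower (median -0.03, camera adjusted p = 0.991). These 3 genes were named because they alone passed over a list.

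Markers of blood cells did not pass the test, though most had lower values in low iCrit endometrium. Of the erythroid and platelet markers 9 of 10 were lower, with a median of -0.41 (camera adjusted p = 0.0536, exact permutation p = 0.0375, or 0.581 adjusted over the lists), and HBB, the beta globin, stood at 2000 ± 1119 and 2912 ± 1306 (SD, n = 7 and 8). The erythroid list was called by camera after quantile normalization, after median centring, without the intensity trend, without the 4 libraries apart on the first component, and without low iCrit replicate 1 or 7 or high iCrit replicate 3 or 8. With an estimated correlation its adjusted p in all libraries was 0.631, and by fry the adjusted p was 0.329. Of the neutrophil and eosinophil markers 11 of 14 were lower (median -0.28, camera adjusted p = 0.233), with low iCrit replicate 2 at a list mean of -1.52 and the other low iCrit gilts at -0.57 to 0.41. S100A9, a calcium-binding protein of neutrophils, stood at 20819 ± 13064 in low and 37452 ± 17395 in high iCrit gilts. MMP9, another member of that list, stood at 13.5 ± 6.28 and 14.0 ± 8.37. Values from whole tissue do not show which cells gave the S100A9 signal. HBB and S100A9 were not named by the rule for genes.

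None of the other immune lists was called with all 15 libraries. The T and NK cell markers had 20 of 38 members lower (median -0.02, camera adjusted p = 0.772), the B and plasma cell markers 13 of 20 lower (median -0.13, 0.387) and the macrophage and dendritic cell markers 15 of 24 higher (median 0.03, 0.608). MHC class II genes were lower in 15 of 20 (median -0.04, 0.608), interferon response genes in 38 of 55 (median -0.10, 0.367) and inflammatory cytokine genes in 30 of 47 (median -0.11, 0.244). Complement and innate defence genes were higher in 18 of 30 (median 0.04, 0.533). The interferon list was called without low iCrit replicate 2, without high iCrit replicate 3 and without the 3 libraries apart, and the inflammatory list without the 4 libraries apart on the first component. Their adjusted p with an estimated correlation and all libraries were 0.938 and 0.8292.

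Of the structural cell types, endothelial markers were higher in 14 of 19 (median 0.09, camera adjusted p = 0.119), smooth muscle markers in 11 of 20 (median 0.05, 0.608) and ciliated cell markers in 21 of 33 (median 0.05, 0.171). Epithelial and junction markers were lower in 26 of 36 (median -0.14, 0.184), as were 25 of 38 genes of luminal and glandular secretion (median -0.11, 0.213). The endothelial list was called with the stricter filter, without low iCrit replicate 2 or 3 or high iCrit replicate 1, 5 or 8, and without the 3 libraries apart. The ciliated list was called without low iCrit replicate 3 or 7 or high iCrit replicate 4, 6 or 8, with the reads covariate and without the 4 libraries apart on the first component. The secretory list was called without high iCrit replicate 4 and without those 4 libraries, and the epithelial list without low iCrit replicate 1. With an estimated correlation and all libraries the adjusted p were 0.938 for the ciliated list and 0.8292 for the other 3. Markers of conceptus trophoblast were lower in 12 of 20 (median -0.12, 0.995), and high iCrit replicate 8 held the highest mean of that list, 1.88 above the average of all libraries.

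Among the other pathways, ion and water transport genes were higher in 32 of 51 (median 0.09, camera adjusted p = 0.166) and angiogenesis genes in 21 of 30 (median 0.07, 0.234). Extracellular matrix genes were higher in 26 of 47, with a median of 0.04 and an upward camera test (0.301) but a mean of -0.05. Cholesterol and lipid genes were lower in 24 of 37 (median -0.16, 0.158), cell cycle genes in 36 of 49 (median -0.16, 0.400), prostaglandin genes in 14 of 25 (median -0.03, 0.855) and immediate-early and heat shock genes in 22 of 31 (median -0.11, 0.546). Without low iCrit replicate 2 the ion transport, angiogenesis and matrix lists were called, and angiogenesis also without the 3 libraries apart. Cholesterol and cell cycle lists were called without low iCrit replicate 1 or 6 and without the 4 libraries apart on the first component, and the cholesterol list also without high iCrit replicate 3. With an estimated correlation and all libraries the adjusted p were 0.724 for ion transport, 0.8292 for angiogenesis and cholesterol and 0.938 for matrix and cell cycle. In all lists that were not called 0 members passed over all genes, and adjusted over the list alone 0 passed except the 3 genes named above.

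The largest axis of variation among the mRNA libraries did not follow iCrit. The first principal component held 21.6% of the variance and set low iCrit replicates 1 and 6 and high iCrit replicates 4 and 6 apart, at 50.8 to 60.4, from the other 11 libraries, at -45.3 to 3.64 (group means -1.54 and 1.34, exact permutation p = 0.869). SULT1E1, the estrogen sulfotransferase, reached 7751, 3113, 3497 and 5003 in those 4 libraries and at most 1446 in the rest, and MMP8, a neutrophil collagenase, 19468, 5059, 10423 and 13144 against at most 4636. Both genes were picked after their values were seen. Without these 4 libraries limma called 0 genes, with 1806 at an unadjusted p under 0.05, and camera called 9 gene lists, without the growth factor list (adjusted p = 0.274) and the stromal list (0.878).

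**Figure D2:**
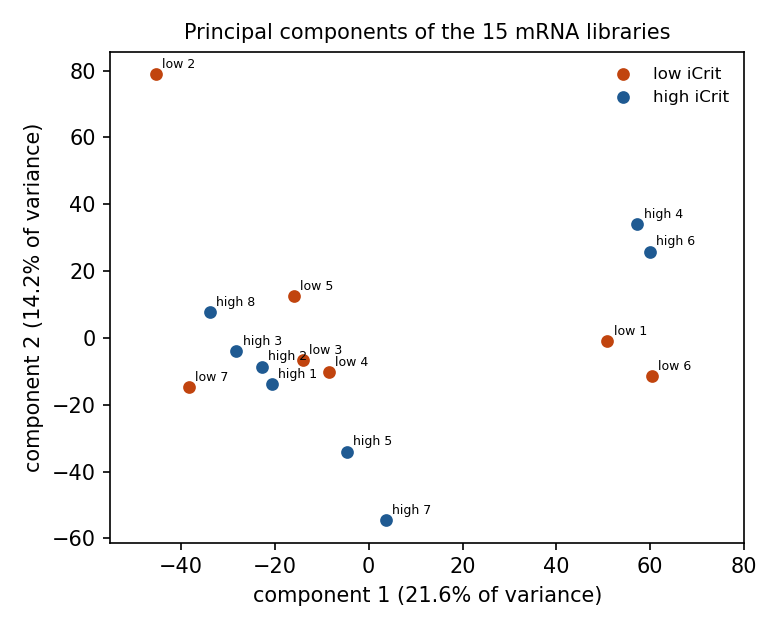
First and second principal components of log2(value + 1) in the 15 mRNA libraries (axes in component units, with 21.6% and 14.2% of the variance), coloured by iCrit group, 1 point per animal. Low replicates 1 and 6 and high replicates 4 and 6 lie to the right of all others, and low replicate 2 lies at 79.0 on the second component.

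Some let-7 miRNAs, a family of conserved regulators, tended to higher values in low iCrit endometrium. let-7e (chromosome 6, 51858385 to 51858406) stood at 32775 ± 3998 in low and 27915 ± 1619 in high iCrit gilts (SD, n = 7 and 8), and let-7f at 549370 ± 77261 and 465460 ± 46120 for the locus on chromosome X (51801782 to 51801803), with nearly the same values for its identical copy on chromosome 3. Positions of miRNAs are printed as deposited and may not be those of Sscrofa11.1. miR-10b, from a HOX cluster (chromosome 15, 91419030 to 91419051), stood at 671520 ± 98028 and 562830 ± 63250. let-7d-3p, the other arm of a let-7 precursor (chromosome 3, 44867331 to 44867352), went the other way, at 1188 ± 66.8 against 1499 ± 130, and lay below every high iCrit gilt in 7 of 7 low iCrit gilts. The main arm, let-7d-5p, differed by -0.21 on the log2 scale, and let-7c and both let-7a loci by 0.08, 0.06 and 0.06. miR-361-5p, miR-1343 and miR-423-3p differed by -0.19, -0.23 and -0.22 on the log2 scale.

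limma called 0 of 302 miRNAs (lowest adjusted p = 0.392), with 21 at an unadjusted p under 0.05, where chance would give 15.1. Of these 10 were higher and 11 lower, a split that became 13 and 5 after quantile normalization and 21 and 4 after median centring. Leaving out 1 animal also moved it, to 3 and 15 without low iCrit replicate 6, 4 and 18 without high iCrit replicate 1, 4 and 15 without high iCrit replicate 5, 5 and 13 without low iCrit replicate 3 and 10 and 6 without high iCrit replicate 4. camera called 1 of 9 lists, let-7 and miR-98, with 9 of 11 members higher, a median of 0.10 and an adjusted p of 0.00430. With an estimated correlation the adjusted p was 0.674, after quantile normalization 0.167, and with 1 entry per mature name, since let-7a and let-7f each have 2 loci among the 11, it was 0.0541. The list mean lay above the high iCrit mean in 3 of 7 low iCrit gilts (exact permutation p = 0.258), and the median was 0.0341 without low iCrit replicate 4 and 0.149 without low iCrit replicate 5. Adjusted over the list alone 1 member passed, let-7d-3p, in the opposite direction, and 0 passed over all miRNAs.

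The other miRNA lists were not called. Over all 302 miRNAs the median log2 difference was -0.07, with 34.4% higher in low iCrit gilts, and it was 0.00 after quantile normalization and 0.01 after median centring. The list of miR-17-92 and paralogous clusters, with both arms of miR-92b from a locus of its own on chromosome 4, was lower in 14 of 15 members (median -0.13, camera adjusted p = 0.110), and the list of the imprinted DLK1-DIO3 cluster was higher in 4 of 6 (median 0.16, 0.0656). Of those 6, miR-545-3p (-0.34) lies on chromosome X, outside the cluster, while the others lie on chromosome 7. That list was called without low iCrit replicate 2, 3 or 4 or high iCrit replicate 4, 5, 7 or 8, with the first component as a covariate and without the 3 libraries apart, and the miR-17-92 list without low iCrit replicate 2, high iCrit replicate 1 or 8, or the 3 libraries apart. The erythroid miRNAs miR-144, miR-451 and miR-486 were lower in 3 of 3 (median -0.41, 0.201). The miR-29 and miR-30 families were lower in 12 of 15 (median -0.12, 0.201), muscle miRNAs in 10 of 12 (median -0.15, 0.201), the miR-183-96-182 cluster in 3 of 3 (median -0.19, 0.201) and the miR-181 and miR-221 families in 8 of 9 (median -0.08, 0.622). The erythroid miRNA list was called without low iCrit replicate 7 and the miR-183-96-182 list without the 3 libraries apart. The adjusted p of these 4 lists with an estimated correlation and all libraries was 0.674. Leukocyte miRNAs were lower in 6 of 7 with a median of -0.03, while camera pointed upward (0.660). The miR-200 family, ciliated cell and endothelial lists had under 3 tested members and were not tested as lists. Their members miR-429, miR-34c and miR-126-3p differed by -0.13, 0.06 and 0.06.

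Low iCrit gilts did not differ detectably from high iCrit gilts in how much they varied among themselves. The median log2 ratio of the SD in low over high iCrit gilts was -0.04 over 16819 genes (permutation p = 0.851, 100 draws) and 0.12 over 302 miRNAs (permutation p = 0.366). Permuted labels gave ratios from -0.49 to 0.41 for genes and from -0.31 to 0.23 for miRNAs.

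Markers of T and NK cells and of ciliated cells varied together in the mRNA and miRNA libraries of the same animal. The mean of 38 T and NK cell genes followed the mean of 7 leukocyte miRNA loci such as miR-150 and miR-142 across 15 animals (Pearson r = 0.877, permutation p = 7.0e-05, adjusted over 6 relations 0.00042, Spearman rho = 0.757, permutation p = 0.00174, adjusted 0.00702). Without high iCrit replicates 2 and 8, the animals farthest from the median, r was 0.654 (permutation p = 0.0148). Macrophage and MHC class II genes were highest in the same animals, with list means of 0.82 and 0.61 in high iCrit replicate 2 and 0.68 and 0.82 in high iCrit replicate 8. The mean of 33 ciliated cell genes, such as FOXJ1 and dynein genes, followed miR-34c, a miRNA of multiciliated cells (r = 0.805, permutation p = 0.00038, adjusted 0.00114, rho = 0.746, permutation p = 0.00234, adjusted 0.00702), with r = 0.833 without low iCrit replicate 2 and high iCrit replicate 6. Within the low and high iCrit groups r was 0.72 and 0.915 for the T and NK cell relation (exact permutation p = 0.0593 and 0.00523) and 0.768 and 0.841 for the ciliated one (exact permutation p = 0.0401 and 0.0104).

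The other marker pairs did not pass. Epithelial markers and miR-429 had r = 0.356 (permutation p = 0.193, adjusted 0.386) and rho = 0.539 (permutation p = 0.0405, adjusted 0.0809). Smooth muscle markers and muscle miRNAs had r = 0.159 (permutation p = 0.569, adjusted 0.722) and rho = 0.104 (permutation p = 0.714, adjusted 0.856). Neutrophil markers and leukocyte miRNAs had r = -0.04 (permutation p = 0.889, adjusted 0.889) and rho = -0.20 (permutation p = 0.464, adjusted 0.696). The tested leukocyte loci were those of miR-142, miR-146a, miR-146b, miR-150 and miR-155. miR-223, a miRNA of neutrophils, and miR-342 were on the list but not among them. This pair therefore cannot decide whether neutrophil markers follow a neutrophil miRNA. Across all 15 animals the first components of the assays had r = 0.222 (permutation p = 0.423) and rho = 0.232 (permutation p = 0.406). Because 4 mRNA libraries stood apart on the first mRNA component, the components were also compared among the other 11 animals. There r was 0.178 (permutation p = 0.602) and rho 0.045 (permutation p = 0.903), and these p entered the adjustment over the relations.

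**Figure D3:**
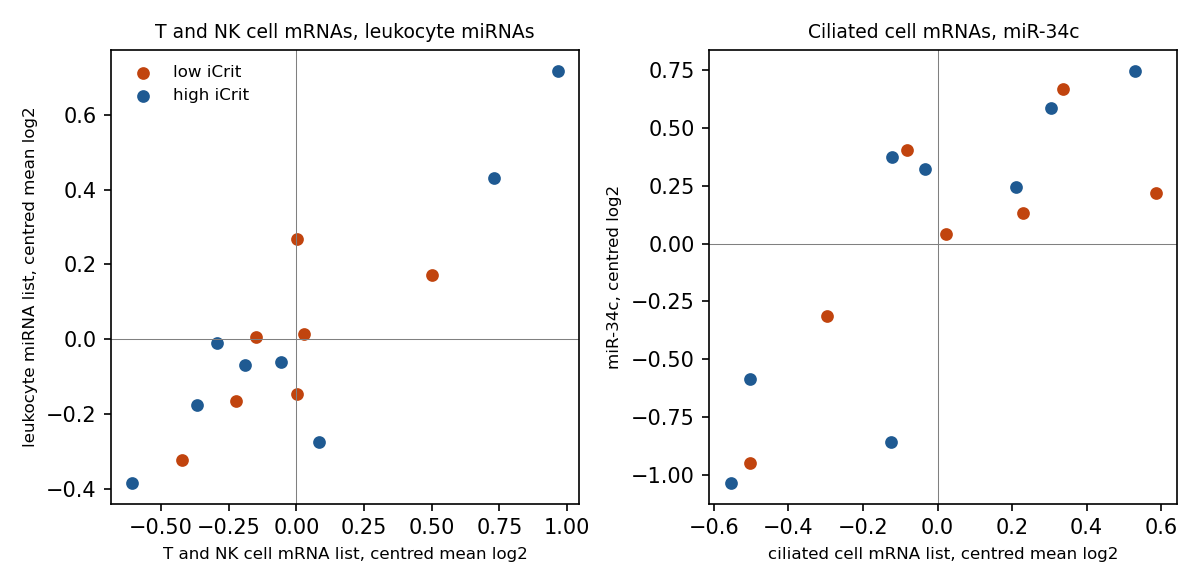
Left, mean of T and NK cell genes (horizontal) against mean of leukocyte miRNAs (vertical) per animal, and right, mean of ciliated cell genes against miR-34c. Axes are centred log2(value + 1), and points are 7 low and 8 high iCrit gilts, with r = 0.877 on the left and r = 0.805 on the right.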

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

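Every test of an explanation in this part was chosen after the result was seen, except the counts over other splits of the animals, and the conditions for excluding the ribosomal, mitochondrial and conceptus explanations were revised after their first results, each time making exclusion harder, while the test of a few reads, first undecided, was replaced by one on estimated reads that argues against it.

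An animal stood apart from its group by Dixon's test in 14 of 188 groups of values (7.45%), where chance gives about 5%. High iCrit replicate 7 had the highest values of its group for NDUFB9 (5341, others up to 3583), NDUFS8 (3138, others up to 2140) and NDUFA10 (3537, others up to 2691), and its oxidative phosphorylation mean was 0.68 (others up to 0.14). Low iCrit replicate 2 had a PTGS2 value of 1140 (others from 4802), a conceptus-estrogen list mean of -1.39 (others from -0.21) and an epithelial list mean of -0.59 (others from -0.07). High iCrit replicate 8 had a conceptus trophoblast mean of 1.88 (others up to 0.36) and a neutrophil mean of -0.55 (others from 0.13). High iCrit replicate 2 had an inflammatory cytokine mean of 0.89 (others up to 0.13), and low iCrit replicate 6 a complement mean of 0.59 (others up to 0.06). C9H1orf21 was 1222 in low iCrit replicate 1 (others from 1804), PGR 216 in low iCrit replicate 5 (others from 277) and MMP9 2.18 in low iCrit replicate 7 (others from 10.3).

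Ribosomal protein and oxidative phosphorylation genes were lower together in low iCrit gilts, and the median change of all genes went from -0.12 in the fifth with the shortest gene span to 0.08 in the fifth with the longest. For the ribosomal genes, removing each library's trend on gene span left a median of -0.20 (fry p = 0.0424, exact permutation p = 0.0389, both unadjusted). Leaving out high iCrit replicate 7 left -0.21 (fry p = 0.0171, exact permutation p = 0.0204, both unadjusted). With all libraries the median was -0.29, so each took up part of the difference and neither alone the whole of it. The 2 corrections were not made together. Gene span includes introns, so a trend on transcript length was not tested and stays open. Depth stays open, since with estimated reads as a covariate the median was -0.21 but fry p was 0.0682, and the ribosomal mean was related to estimated reads (r = -0.619, permutation p = 0.0229, rho = -0.37, permutation p = 0.176), with r = -0.773 among low and -0.710 among high iCrit gilts and r = -0.429 without low iCrit replicates 3 and 4 (permutation p = 0.149). For oxidative phosphorylation the medians were -0.15 with the span trend removed, -0.12 without that library and -0.14 with the reads covariate (fry p = 0.275, 0.273 and 0.334, exact permutation p of the list 0.158), so none of these nor chance is excluded. Chance between animals also stays open for the ribosomal genes, with an exact permutation p of 0.0131, the smallest of 31 lists and 0.405 after adjustment, so a lower level of both in low iCrit gilts remains 1 of several open readings.

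High iCrit replicate 8 had the highest values of 8 of 20 trophoblast markers, among them PAG6, a pregnancy-associated glycoprotein, and IFNG, which T and NK cells also make and whose markers averaged 0.73 there: PAG6 was 7446 (at most 109 elsewhere), IFNG 2804 (at most 203), HAND1 471 (at most 26.1), GATA3 278 and TFAP2C 96.3. A candidate explanation is conceptus tissue collected with the endometrium, for which 3 of the 15 list members not seen first (CYP17A1, CYP11A1 and EOMES) were highest in this library where chance gives 1 (exact binomial p = 0.0738, one-sided). EOMES is also on the T and NK cell list, so its value in this library need not come from a conceptus. The test treats members of 1 library as independent and leaves out PAG6, IFNG, HAND1, GATA3 and TFAP2C, which were seen first. This count is undecided, since 3 members against 1 by chance gave an exact binomial p of 0.0738. KRT18, GATA2 and APOA1 are abundant in every library and would hide a small share of trophoblast. That does not cover TTR (82.0 there, up to 146 elsewhere) or LIN28A (3.57, up to 11.2 elsewhere), which were low and also not highest there. A few reads of very low genes is argued against, since all 8 members highest there had at least 10 estimated reads, from 44.0 for EOMES to 8350 for PAG6, although the first test, with 2 of the 8 above the median tested gene, had left it undecided. PLET1, picked after its value was seen, was 3947 there and at most 122 in the other libraries.

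Other splits of the same animals gave counts as large as the real one too often to exclude chance, wherever the real count was above 0. Each count below is of 100 splits with the real one included. For genes at an unadjusted p under 0.05 (real 1200) 16 did, with up to 2427 in the others. For gene lists (real 5) 90 splits did, with up to 18 and a median of 9 among the 99 others, all of which called some list. For miRNAs at an unadjusted p under 0.05 (real 21) 20 did, with up to 76, and for miRNA lists (real 1) 82 did, with up to 5 and a median of 2 among the others. For genes and miRNAs called the real counts were 0, which all 100 splits reach by construction, so this says nothing about chance, and of the 99 other splits 8 called any gene (up to 65) and 6 any miRNA (up to 18). The real grouping thus called fewer gene and miRNA lists than the median of the other splits. What the splits with many calls have in common was not tested.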

How the results depend on the processing

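The fits with a covariate, with the span trend removed, without the libraries apart or with 1 entry per miRNA name, the spread without low iCrit replicate 2 and the other settings of the mRNA and miRNA relations were tests chosen after the data had been seen, and the others were planned. Limma called 0 genes and 0 miRNAs under every alternative run, and the lowest adjusted p were 0.277 for genes (quality weights) and 0.0641 for miRNAs (no filter), while the genes at an unadjusted p under 0.05 numbered 799 with the stricter filter, 1985 with quality weights, 1806 without the 4 libraries apart on the first component, 915 with the span trend removed and 939 to 1688 when 1 animal was left out (without low iCrit replicates 4 and 6). With the span trend removed 439 were higher and 476 lower. For miRNAs the same count was 32 with the first component as a covariate, 41 without the 3 libraries apart, 12 with the stricter filter and 16 to 36 with 1 animal left out, the highest without low iCrit replicate 2, while without low iCrit replicate 7 it was 33.

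Gene lists called numbered 2 with quality weights, 9 without the 4 libraries apart on the first component, and 0 with an estimated correlation or fry. Leaving out 1 animal gave 3 (without high iCrit replicate 2) to 10 (without low iCrit replicate 2), with 9 without low iCrit replicate 1 and 8 without high iCrit replicate 3 or 8. miRNA lists called numbered 0 after quantile normalization, with 1 entry per mature name (let-7 and miR-98 adjusted p = 0.0541), with an estimated correlation and by fry, 2 with the first component as a covariate and 4 without the 3 libraries apart, low iCrit replicate 2 and high iCrit replicates 7 and 8. With 1 animal left out they numbered 1 to 3, with 3 without low iCrit replicate 2 or high iCrit replicate 8 and 2 without low iCrit replicates 3, 4 or 7 or high iCrit replicates 1, 4, 5 or 7. For an estimated correlation and fry the tests allow for members that vary together, and otherwise the cause was not tested. Over 185 fits of the 6 called lists 156 kept direction and call, 29 kept direction only and 0 reversed. These lists were chosen because they were called in the same data, so their kept direction is no support.

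Of 48 named genes and miRNAs 40 kept their direction in every fit, and 47 of 1378 fits reversed the other 8. Without 1 animal ESR1 ranged from -0.0860 to 0.15, PGR from -0.12 to 0.0738, RXFP1 from -0.18 to 0.21, VEGFA from -0.0487 to 0.41, MMP9 from -0.21 to 0.27, PTGS2 from -0.22 to 0.38 and SPP1 from -0.24 to 0.20. With quality weights PGR was 0.0665, RXFP1 -0.0819, PTGS2 0.16 and SPP1 0.0134. With estimated reads as a covariate ESR1 was -0.0660, RXFP1 -0.14 and SPP1 0.16. Without the 3 libraries apart ESR1 was -0.0798, RXFP1 -0.0789, PTGS2 0.20 and SPP1 0.47. With the span trend removed ESR1 was -0.0614, RXFP1 -0.0453, MMP9 0.0115, PTGS2 0.0392 and SPP1 0.00771. Without the 4 libraries apart on the first component PGR was 0.17, RXFP1 -0.22, VEGFA -0.10, WNT7A -0.0248 and PTGS2 0.0558. For these reversals the cause was not tested.

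The spread within groups did not pass with the median absolute deviation (-0.11 for genes and 0.17 for miRNAs, permutation p = 0.584 and 0.248) or without low iCrit replicate 2 (-0.17, permutation p = 0.376). The T and NK cell relation had r from 0.830 to 0.877 and the ciliated relation r from 0.756 to 0.880 with a pseudocount of 0.1, after quantile normalization and without the 3 libraries apart, with all adjusted p at most 0.00306. Count models were not run because the values are not counts, and 1 value per symbol was not run because entries are genes, not transcripts. No paired analysis was possible because high and low iCrit gilts share no numbers in the labels.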

Other observations

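The tests of the first component in this part were chosen after the result was seen, and the genes here were picked after their values were seen.

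ACOD1, which makes the antimicrobial metabolite itaconate in activated myeloid cells (chromosome 11, 49077152 to 49088218), stood at 696 ± 609 in low and 3528 ± 2048 in high iCrit gilts (SD, n = 7 and 8), a log2 difference of -3.01 ± 0.76 (SE) with an limma adjusted p of 0.672. All 7 low iCrit gilts lay below the high iCrit mean and 5 below every high iCrit gilt, yet the low iCrit values ran from 33.0 to 1550 and the high ones from 1009 to 6712. AKR1B1, an aldo-keto reductase with prostaglandin F synthase activity, ranged from 2445 in low iCrit replicate 2 to 151360 in high iCrit replicate 7, with means of 29590 ± 33462 and 56662 ± 43567.

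RLN2, a relaxin gene, stood near the floor, at 27.0 ± 22.9 in low and 9.84 ± 7.43 in high iCrit gilts (SD, n = 7 and 8), with an limma adjusted p of 0.672. TIMP1, a metalloproteinase inhibitor, stood at 1232 ± 747 and 1860 ± 650 (limma adjusted p = 0.688). EGFR, the epidermal growth factor receptor, reached 11989 in low iCrit replicate 2 and 1475 in high iCrit replicate 7, with group means of 5965 ± 2791 and 4313 ± 1932.

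The 4 mRNA libraries apart on the first component (low iCrit replicates 1 and 6, high iCrit replicates 4 and 6) were also high for PENK, the proenkephalin gene (863, 1104, 357 and 1153, at most 245 elsewhere). Of the 4, 0 had estimated reads outside the range of the other 11, which held both the shallowest and the deepest library (23.7 and 63.5 M). The 4 had 29.2, 44.7, 33.5 and 38.0 M, with shallower and deeper libraries among the others. That argues against depth of the libraries as the only cause, and a lesser part of depth was not tested. A structure of the mRNA library preparation alone stays open, since in the miRNA values the distance of these 4 animals from the other 11 was 0.25 against a median of 0.24 over all 1365 sets of 4 (exact permutation p = 0.344, one-sided). This test replaced a first one, in which 0 of the first 3 miRNA components had the 4 at one end, an outcome first read as going with that explanation. Of the 4 animals, 3 had the highest miR-34c values of the 15 (157220 in high iCrit replicate 6, 148920 in low iCrit replicate 6 and 140590 in high iCrit replicate 4, with 96512 in low iCrit replicate 1). This miRNA was picked after its values were seen, so it does not count against that explanation. A difference between the animals, such as the stage of the conceptuses, stays open as well and was not tested.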
